A study of Mus musculus with 38 samples.

How the data were processed

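The series holds stranded total RNA sequencing of mouse embryonic stem cells of 129S6/SvEvTac background, grown on gelatin in serum and LIF, per the labels' protocols. There are 38 libraries in 17 groups. The first batch (26 libraries, 13 groups of 2) has wild-type cells with DMSO for 1 h or 24 h, 10 uM BRM014 for 30 min, 1 h, 3 h, 6 h or 24 h, 10 uM inactive analog for 1 h or 24 h, and washouts of 30 min and 1 h after 1 h of BRM014 or of 6 h and 24 h after 24 h of BRM014. The second batch (12 libraries, 6 groups of 2) has wild type, Ino80ko and Snf2hko with DMSO or 10 uM BRM014 for 24 h. Both compounds were dissolved in DMSO at 10 mM. The labels give no dose for the washout groups, no vehicle at 30 min, 3 h and 6 h, and no washed vehicle. The protocols call the replicates biological but do not say which cultures or days they come from, so p-values measure only the spread between these samples, part of which may be technical.

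The deposited values are counts per gene, 1 column per library, with no normalization. Per the submitters' processing notes, bcl2fastq 2.17 and STAR were used with mouse build GRCm38 (mm10). The counting program and its annotation are not given in the sources used here. The counts cover 55385 genes, all 38 columns were matched to samples, and 0 were unmapped. Symbols came from the deposited table, and 55144 gene identifiers matched GENCODE M21. Of 21897 protein-coding genes 6709 have 0 counts in every library. These include 4189 of 4191 genes with several exons that overlap another gene on the same strand, 1424 of 1435 genes with a single exon and 13 of 13 mitochondrial genes, against 1096 of 16271 genes with several exons and no such overlap. Smarca4, Smarca5, Sox2, Tfcp2l1 and Otx2 are among the genes listed at 0, so nothing can be said of their expression.

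Totals were 19.3 to 23.1 M counts per library in the first batch (median 21.6) and 21.9 to 44.5 M in the second (median 41.3), with 14708 to 16778 genes detected and 4.32% to 5.15% of counts on the 10 highest genes. None of the 19 pairs of libraries within a group and batch was identical (lowest correlation of log2 CPM 0.9951), and all varied by more than counting error (chi-square per degree of freedom 2.04 to 25.36). At this depth the 95% interval of a 2 against 2 comparison spanned a median of ± 0.19 log2 for well-expressed genes.

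Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group (minimum count 10, minimum total 15), TMM factors (0.948 to 1.041), robust quasi-likelihood F-tests, and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. The 24 h effect in wild type used the 8 libraries of both batches with batch as a term (11787 genes, biological coefficient of variation 9.2%). Other comparisons used 1 fit of the 26 libraries of the first batch (12517 genes, 6.2%, 13 residual degrees of freedom) or of the 12 libraries of the second (13130 genes, 6.6%, 6 residual degrees of freedom), which share an estimate of the spread because each group has 2 libraries. Treatments of 3 h and 6 h were set against the mean of DMSO 1 h and DMSO 24 h. Differences between genotypes, times and batches were tested as interactions. In total 28 comparisons were made, each adjusted on its own.

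A total of 27 gene lists were written from textbook knowledge. The list of mitochondrially encoded genes could not be tested, as all of its genes had 0 counts, and the other 26 were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Lists called with the preset value were often not called with the estimated one, and both are given. Members called are counted over all genes and adjusted over the list alone. Named genes were the ATPase genes Smarca4, Smarca2, Ino80 and Smarca5, plus up to 10 rises and 10 falls with the largest log2 change in each of the BRM014 comparisons at 24 h, 1 h and 6 h and both genotype comparisons (5 and 5 in the others). They had to be called, change at least 2-fold in those main comparisons, have a mean log2 CPM of at least 2, separate the libraries of both groups within a batch, and have a symbol that is no predicted model. Up to 4 called members with the smallest adjusted p were named per list. Results for 4 genes that this rule names are not reported here. A gene with 0 counts in a group is given as a bound against a floor of 3 counts over the group. Such bounds, and the ratios of genes with 1 to 3 counts, cover counting error only. The comparisons, tests, lists, naming rule and most alternatives were set before the data were examined.

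Recovery after washout was followed in genes chosen in the other batch (called in wild type of the second batch with a change of at least 2-fold) or, for 1 h, between BRM014 and the analog. Correlations across genes are Pearson values of fold changes that share no library unless stated, and the effect of a shared vehicle group was computed in 20 simulated draws. The procedure was tested on simulated counts, drawn from the model that edgeR assumes with the mean, spread and library sizes of the real data. Known changes were added to 200 genes. Such counts hold no batch or other treatment differences, so the shares below show only how the model recovers its own data. For the 24 h effect, 94% of 67 genes changed 1.5-fold and 98.5% of those changed 2-fold were recovered, with 9.8% of calls false. For 1 h the shares were 89.6% and 98.5% (7.2% false), for Snf2hko 92.5% and 100% (4.9%), for the Ino80ko interaction 65.7% and 97% (4.9%), and for the difference between batches 64.2% and 95.5% (8%). A changed list of 15 genes was called in each of the 5 tests, and 0 of 26 unchanged lists. The simulated genes varied independently of one another, so this cannot show how the preset correlation behaves where genes vary together.

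Alternatives were DESeq2 1.42.0 Wald tests, RLE factors, library totals, no filter on low counts, a replicate block, no batch term, fits of the compared libraries only, either vehicle alone for 3 h and 6 h, other gene choices for recovery and correlations, and leaving out each library in turn. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.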

Results

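Mouse embryonic stem cells in serum and LIF received BRM014, a blocker of the ATPases BRG1 (Smarca4) and BRM (Smarca2) that drive SWI/SNF chromatin remodelling. RNA was collected from 30 min to 24 h of treatment and after washout, beside vehicle (DMSO) and an inactive analog. Lines labelled Ino80ko and Snf2hko, named for the ATPases of the INO80 and ISWI remodellers, received DMSO or BRM014 for 24 h. The comparisons ask which transcripts need SWI/SNF activity, and how fast they respond and recover. They also ask how the response relates to changes in lines labelled for loss of another remodeller. Fold changes are log2 ± standard error, and levels are CPM (counts scaled to library size) ± SD over the libraries of a group.

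Inhbb, the activin beta B subunit, fell furthest after 24 h of BRM014, from 246 ± 18.9 to 9.18 ± 0.997 CPM (-4.73 ± 0.09, adjusted p = 1.87e-15, 4 libraries against 4). Trh, which encodes a hypothalamic releasing hormone, fell from 193 to 14.8 CPM (-3.72 ± 0.16), and Tgm1, a cross-linker of epidermal envelopes, from 161 ± 13.7 to 15.3 ± 1.03 (-3.39 ± 0.07, adjusted p = 3.36e-15). Vcam1, an adhesion molecule of endothelium, rose from 0.166 ± 0.0795 to 8.48 ± 0.851 CPM (5.77 ± 0.24, adjusted p = 1.43e-11). Among well-expressed genes, the matrix protein gene Coch rose from 16.9 ± 3.57 to 119 ± 6.10 CPM (2.81 ± 0.10), and Fgfbp1, whose product releases FGFs from matrix, from 16.3 ± 2.11 to 111 ± 6.84 (2.76 ± 0.09, adjusted p = 1.33e-12). The other large rises were Trim43b, Lix1, Car14, Thbs2, Bmpr1b, Themis and Tmprss11d (2.84 to 4.25), and the other large falls were Igsf21, Skor1, Emp1, Hopx, Krt17, Krt42 and Mymx (-4.47 to -3.42). The edgeR quasi-likelihood test with batch as a term called 5842 of 11787 genes, 2923 higher and 2919 lower, of which 593 and 947 changed at least 2-fold. The rises of Trim43b and Thbs2 differed between batches (-1.90 ± 0.46 and -2.49 ± 0.44 for the second minus the first), and Skor1 stood at 8.91 CPM in 1 vehicle library against 11.1 to 11.3 in the others.

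**Figure D1:**
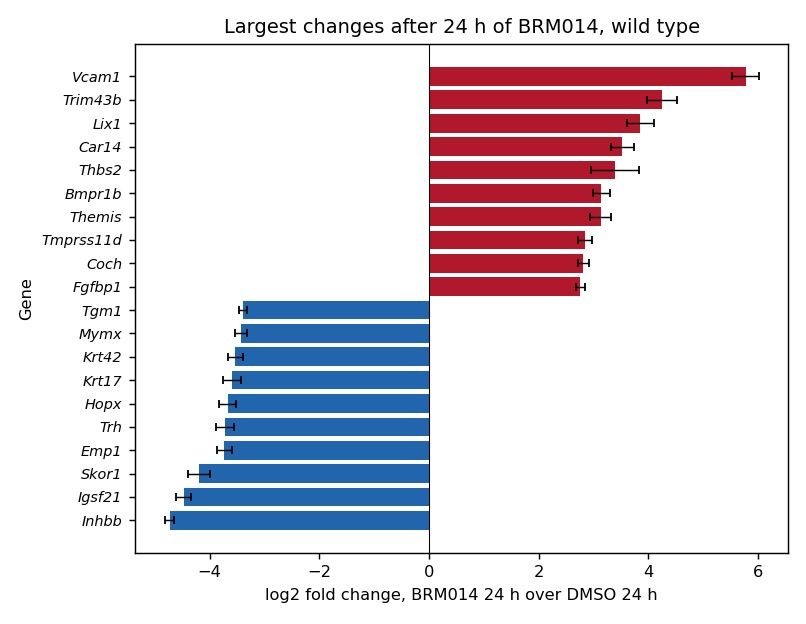
Log2 fold change of the 10 genes with the largest rise (red) and the 10 with the largest fall (blue) after 24 h of BRM014 against DMSO in wild-type cells, 4 libraries per group, bars with standard errors from the fit. The changes run from -4.73 for Inhbb to 5.77 for Vcam1.

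Pluripotency genes moved both ways after 24 h of BRM014. Fgf4, the autocrine signal that primes stem cells for differentiation, fell from 328 to 133 CPM (-1.30 ± 0.09, adjusted p = 4.62e-08), Bmp4 fell by 1.79 ± 0.08 and the de novo methyltransferase Dnmt3a by 1.12 ± 0.07, while Dppa2 rose (0.98 ± 0.06). Of 17 core pluripotency genes 8 rose and 4 fell, and of 14 naive genes 4 rose and 7 fell, and neither list passed camera (adjusted p = 0.383 and 0.338). Primed markers Fgf5 and Zic2 rose (2.19 ± 0.25 and 1.48 ± 0.17), with 4 of 10 formative genes higher and 4 lower (adjusted p = 0.793). The size of the change differed between batches for Zic2 and Fgf4 (-0.94 ± 0.18 and 0.53 ± 0.11 for the second minus the first). Germline genes rose most uniformly: Mael, a piRNA pathway factor, went from 21.2 to 64.1 CPM (1.60 ± 0.07, adjusted p = 2.75e-11), and 13 of 17 were called higher and 0 lower (13 adjusted over the list alone; list adjusted p = 0.00103, and adjusted p = 0.577 with an estimated correlation). The inactive analog raised that list at 24 h as well (7 of 17 higher, 0 lower; 8 and 0 adjusted over the list alone; Mael 0.92 ± 0.09; adjusted p = 4.8e-05, and adjusted p = 0.0975 with an estimated correlation). At 1 h the analog had instead lowered the list (median -0.21, camera adjusted p = 0.000705, and adjusted p = 0.356 with an estimated correlation). The vehicle itself was lower in germline genes at 24 h than at 1 h (camera adjusted p = 0.0403, and adjusted p = 0.605 with an estimated correlation), a call lost without replicate 1 of either group.

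Signalling targets shifted at 24 h as well. The Wnt targets Sp5, Axin2 and Ccnd2 fell (-3.14 ± 0.28, -1.97 ± 0.14 and -1.47 ± 0.08), with 7 of 11 in that list lower and 1 higher, the same counts when adjusted over the list alone (adjusted p = 0.0276, and adjusted p = 0.577 with an estimated correlation). That call was lost without DMSO 24 h replicate 4 (adjusted p = 0.052). Lefty1 and Lefty2, feedback inhibitors induced by Nodal, fell by 2.61 ± 0.14 and 2.56 ± 0.09, whereas Id2, a BMP target, rose (1.74 ± 0.09). Sterol enzymes were lower in 11 of 18 and higher in 1 (12 and 2 adjusted over the list alone), led by Insig1 and Idi1 (-0.73 ± 0.07 and -0.71 ± 0.07; list adjusted p = 0.0182, and adjusted p = 0.577 with an estimated correlation). The analog lowered sterol genes too (9 of 18 lower, 0 higher; 10 and 0 adjusted over the list alone; Insig1 -0.38 ± 0.06; adjusted p = 0.000868, and 0.0342 with an estimated correlation). Of 21 SWI/SNF subunit genes 7 rose and 4 fell, among them Smarcd3 (-1.55 ± 0.14), a gene of the muscle and neural complex. Smarca2 itself did not differ detectably (-0.08 ± 0.11, adjusted p = 0.59), and Smarca4 was listed at 0 counts in each of the 38 libraries.

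Both batches carried the 24 h response. Inhbb fell by 4.94 ± 0.09 in the first and 4.56 ± 0.08 in the second (2 libraries per group), Fgfbp1 rose by 2.91 ± 0.09 and 2.61 ± 0.10, and Mael by 1.59 ± 0.09 and 1.60 ± 0.08. Within batches 5727 and 5554 genes were called. Chosen without the pooled fit, 3836 genes were called in both batches, and 3780 of them moved the same way and 56 in opposite directions. Of the 5825 pooled calls present in every fit 5817 had the same sign in both, which the pooled choice of genes favours, and 3762 were called in both with the same sign. Across 12368 genes the fold changes correlated at 0.77, a relation across genes, which are not independent replicates. The p53 targets had a median of -0.91 in the first batch (13 of 18 lower, 2 higher; 14 and 2 adjusted over the list alone; adjusted p = 1.54e-05, and 0.00312 with an estimated correlation). Over DMSO 1 h the first batch's BRM014 24 h libraries had medians of -0.44 and -0.41 in these genes and its DMSO 24 h libraries 0.43 and 0.54. In the second batch the median against DMSO 24 h was -0.03. The direct test of this list between batches had an adjusted p = 7.64e-12, and adjusted p = 0.18 with an estimated correlation. A test of the difference between batches called 408 of 11787 genes, 233 of them more positive in the second.

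Few transcripts had moved within 1 h. Fgf4 fell from 349 ± 4.08 to 227 ± 13.7 CPM (-0.62 ± 0.06, adjusted p = 1.45e-07, 2 libraries per group), and Dusp6, the phosphatase that damps ERK, rose from 168 to 253 CPM (0.59 ± 0.06, adjusted p = 1.45e-07). Vgll3, a cofactor of TEAD factors, rose from 9.23 ± 0.506 to 19.1 ± 2.56 CPM (1.05 ± 0.12, adjusted p = 1.73e-06), and Nfkbid, a regulator of NF-kB, fell from 12.2 to 5.75 CPM (-1.08 ± 0.17, adjusted p = 0.000755). Prdm14, a repressor of FGF signalling in naive cells, fell by 0.41 ± 0.08 and Id2 rose by 0.58. The analog at 1 h also lowered Nfkbid (7.03 CPM, -0.79 ± 0.17, adjusted p = 0.0423) and raised Id2 (0.44 ± 0.09, adjusted p = 0.0414), and neither gene was called between the compounds. At 1 h 75 of 12517 genes were called, 27 higher and 48 lower. Sterol genes were raised as a list (2 of 18 higher, 8 adjusted over the list alone; adjusted p = 4.03e-10, and 0.000416 with an estimated correlation), and stress response genes lowered (1 of 14, 6 adjusted over the list alone; adjusted p = 0.000116, and 0.00517 with an estimated correlation). The analog moved both lists the same way against the same vehicle (adjusted p = 0.00798 and 0.00971, each 0.0649 with an estimated correlation), calls that were lost without DMSO 1 h replicate 2 or inactive 1 h replicate 2 (adjusted p up to 0.151). The count was 30 and 21 without DMSO 1 h replicate 1 or 2, 45 and 17 without BRM014 1 h replicate 1 or 2, and 49 when only the compared libraries were fitted. At 30 min edgeR called 0 genes, with 348 at an unadjusted p under 0.05, and DESeq2 also called 0. As lists, against vehicle of 1 h, immediate early genes were higher (0 of 21 called, 4 adjusted over the list alone; adjusted p = 2.55e-06, and 0.019 with an estimated correlation), and so were stress response genes (0 of 14, 2 adjusted over the list alone; adjusted p = 0.00204, and 0.019 with an estimated correlation), opposite to their direction at 1 h. The stress call was lost without DMSO 1 h replicate 1 (adjusted p = 0.0582).

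Sterol, stress and naive pluripotency genes had parted by 3 h. Vgll3 reached 41.7 CPM against 7.71 in vehicle (2.47 ± 0.09, adjusted p = 2.54e-17), and the stress factor Atf3 79.1 against 24.6 (1.69 ± 0.07). Chac1, a glutathione-degrading target of ATF4, fell from 21.1 to 2.63 CPM (-2.99 ± 0.16) and Cass4 and Fgf15 by 3.37 ± 0.25 and 2.60 ± 0.12. Of 18 sterol genes 16 rose and 1 fell (17 and 1 adjusted over the list alone; Msmo1 0.83 ± 0.05; adjusted p = 1.16e-11, and 0.000151 with an estimated correlation). Of 14 stress response genes 11 fell and 0 rose, the same adjusted over the list alone (adjusted p = 1.5e-09, and 0.000151 with an estimated correlation). Against DMSO 1 h alone the stress list stayed lower (8 of 14 lower, median -0.33; adjusted p = 6.95e-06, and 0.00205 with an estimated correlation). Against DMSO 24 h, itself raised in this list, its median was -0.78. Of 14 naive genes 9 fell and 1 rose, again the same adjusted over the list alone (Prdm14 -1.36 ± 0.08, Esrrb -0.58 ± 0.06; adjusted p = 0.000157, and 0.024 with an estimated correlation). Against DMSO 24 h alone the estimated correlation gave the naive list an adjusted p = 0.124. No vehicle was collected at 3 h, so the mean of the 1 h and 24 h vehicle served; 3902 genes were called, and 2542 and 2513 without BRM014 3 h replicate 1 or 2.

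At 6 h Vgll3 stood at 55.2 CPM (2.87 ± 0.09, adjusted p = 8.43e-20), with Ccno and Kitl, a gene of ciliogenesis and the KIT ligand, also up (2.52 ± 0.13 and 2.15 ± 0.16). Myrf, an activator of myelin genes, fell from 54.9 to 6.35 CPM (-3.11 ± 0.13) and Tnfrsf8, the CD30 receptor, by 3.79 ± 0.31. Esrrb had fallen by 1.20 ± 0.06 and the adhesion gene Pecam1 by 2.14 ± 0.07. Against the same mean of vehicles 6059 genes were called, 3116 higher and 2943 lower. The stress response list stayed low (12 of 14 lower, 0 higher, the same adjusted over the list alone; adjusted p = 7.51e-08, and 0.000697 with an estimated correlation). Its medians were -0.46 against DMSO 1 h alone (adjusted p = 5.06e-06, and 0.0025 with an estimated correlation) and -0.94 against DMSO 24 h alone. The p53 targets were lower against the mean of vehicles (12 of 18 lower, 1 higher, the same adjusted over the list alone; adjusted p = 0.00183, and 0.0194 with an estimated correlation). Against DMSO 1 h alone they were not called (median -0.12, adjusted p = 0.242). Smarca2 was slightly lower (-0.30 ± 0.12, adjusted p = 0.0351).

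Genes that fell at 24 h had moved further by 6 h than genes that rose. Of genes changed at least 2-fold in the second batch, the 950 that fell had medians in the first batch of -0.12 at 1 h, -0.50 at 3 h, -1.04 at 6 h and -1.54 at 24 h. The 601 that rose had medians of 0.01, 0.12, 0.42 and 1.24. Inhbb changed more at 24 h than at 1 h, each against its own vehicle (-4.57 ± 0.11, adjusted p = 4.32e-22), as did Coch in the other direction (3.19 ± 0.17). In that test of the 2 effects, 3952 of 12517 genes differed, 1873 more positive and 2079 more negative at 24 h. These medians carry no test, and the 3 h and 6 h values rest on the mean of vehicles.

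**Figure D2:**
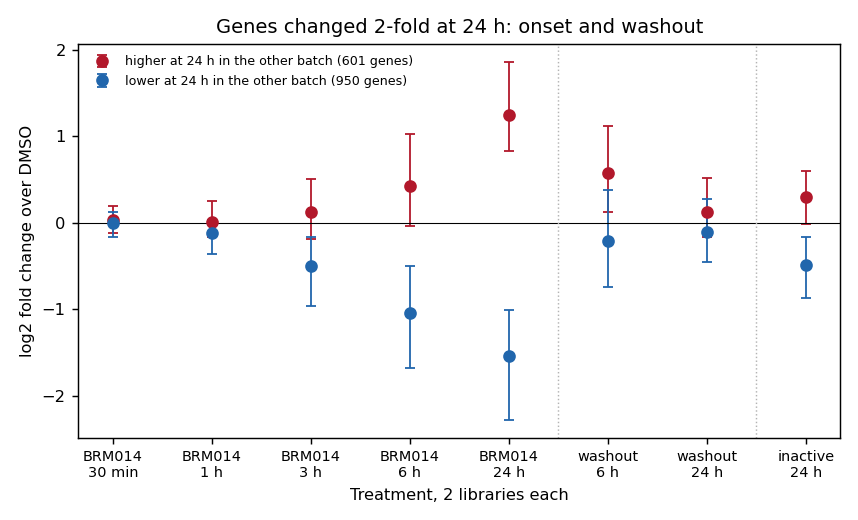
Median log2 fold change over DMSO in the first batch, with quartiles across genes as bars, of the 601 genes raised (red) and 950 lowered (blue) at least 2-fold by 24 h of BRM014 in the second batch, 2 libraries per treatment; BRM014 30 min and 1 h are against DMSO 1 h, 3 h and 6 h against the mean of DMSO 1 h and 24 h, and the rest against DMSO 24 h. Lowered genes reach -1.04 at 6 h when raised genes are at 0.42, and 24 h after washout the medians are 0.12 and -0.11.

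Vehicle itself changed between 1 h and 24 h. Robo4, an endothelial guidance receptor, fell from 20.1 to 5.37 CPM (-1.91 ± 0.14, adjusted p = 1.54e-10), and the gelatinase gene Mmp2 rose (1.36 ± 0.15, adjusted p = 1.17e-07; 2 libraries per group). The p53 targets Trp53inp1, Plk2 and Mdm2 rose by 0.83 ± 0.08, 0.66 ± 0.06 and 0.52 ± 0.06, with 14 of 18 in the list higher and 0 lower, the same adjusted over the list alone (adjusted p = 8.22e-11, and 0.000109 with an estimated correlation). Stress response genes were higher as a list (9 of 14 higher, 1 lower, the same adjusted over the list alone; median 0.45; adjusted p = 8.9e-06, and 0.00194 with an estimated correlation). Germline genes were lower (6 of 17 lower, 2 higher; 7 and 3 adjusted over the list alone; median -0.30; adjusted p = 0.0403, and adjusted p = 0.605 with an estimated correlation). That call was lost without replicate 1 of either group (adjusted p up to 0.301). Serine synthesis genes Psat1 and Phgdh rose as well (0.95 ± 0.05 and 0.72 ± 0.08). The test called 2320 genes, and 1183 and 1147 without DMSO 1 h replicate 1 or 2 and 1202 without DMSO 24 h replicate 2.

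The inactive analog changed transcripts at both times. The 27 genes that 1 h of BRM014 raised and the 48 it lowered had medians of 0.15 and -0.27 in the analog at 1 h, against 0.47 and -0.57 with BRM014, all over the vehicle libraries by which they were chosen. After 1 h 23 genes were called, among them the growth brakes Txnip and Arrdc3, which fell (-0.56 ± 0.07, adjusted p = 0.000109, and -0.50 ± 0.06, adjusted p = 9.7e-05). After 24 h carbonic anhydrase Car2 rose from 150 to 326 CPM (1.11 ± 0.06, adjusted p = 1.58e-13) and Tgm2 from 46.4 to 104 (1.16 ± 0.10), while Ptprv, a phosphatase gene induced by p53, fell from 22.3 to 5.31 (-2.07 ± 0.14, adjusted p = 1.88e-11). Of 18 p53 targets 15 fell and 0 rose (18 and 0 adjusted over the list alone; Plk2 -1.21 ± 0.06, Trp73 -2.21 ± 0.19; adjusted p = 7.75e-18, and 6.53e-06 with an estimated correlation) against 24 h vehicle, which stood above 1 h vehicle in them; over DMSO 1 h the analog libraries had medians of -0.21 and -0.20. At 24 h 2306 genes were called, 1115 higher and 1191 lower. Genes that 24 h of BRM014 raised or lowered in the second batch had medians of 0.30 ± 0.01 and -0.49 ± 0.05 (SD between libraries) in the analog, and across genes its effect correlated with that of BRM014 at 0.42. The 24 h count was 1296 without inactive 24 h replicate 2 and 996 when only the compared libraries were fitted. The 1 h count was 3 and 2 without DMSO 1 h replicate 1 or 2, 2 and 62 without inactive 1 h replicate 1 or 2, and 44 by DESeq2.

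Tested directly at matched time, the compounds differed at 1 h in Dusp6 (253 CPM with BRM014, 164 with the analog, 0.62 ± 0.06, adjusted p = 8.39e-08), Fgf4 (227 and 334, -0.56 ± 0.06, adjusted p = 1.11e-06) and Vgll3 (19.1 and 11.1, 0.79 ± 0.11, adjusted p = 0.000522). The 20 genes called were Pdk4, Dusp6, Adamts1, Pim1, Zfp397, Six4, Bdnf, Arrdc3 and Vgll3, higher with BRM014, and Hmox1, Irf1, Arc, Nr4a1, Kcnk5, Uap1l1, Fgf15, Trib1, Plaur, Fgf4 and Zfp819, lower. The median 95% interval was ± 0.19, and for 8606 of 8631 well-expressed genes it lay within 2-fold. The count was 13 and 2 without BRM014 1 h replicate 1 or 2 and 3 without inactive 1 h replicate 1. As lists, sterol genes were higher with BRM014 at 1 h (0 of 18 called, 3 adjusted over the list alone; adjusted p = 0.0091, and adjusted p = 0.0978 with an estimated correlation; adjusted p = 0.162 without BRM014 1 h replicate 1), and stress response genes were not called (adjusted p = 0.692). At 24 h Inhbb stood at 8.64 CPM with BRM014 and 241 with the analog (-4.80 ± 0.09, adjusted p = 2.38e-25) and Fgfbp1 at 117 and 17.0 (2.78 ± 0.09, adjusted p = 1.97e-19). Kitl and the fibrillin gene Fbn2 were higher with BRM014 (2.85 ± 0.21 and 2.89 ± 0.18), and the keratin gene Krt17 lower (-3.74). That test called 4436 genes, 2168 higher and 2268 lower, with the interval within 2-fold for 7800 of 8631. The germline and sterol lists were not called between the compounds at 24 h (adjusted p = 0.256 and 0.191), and the only call was a higher 2-cell-like list with BRM014 (adjusted p = 0.0346, and adjusted p = 0.401 with an estimated correlation), which was lost without BRM014 24 h replicate 1 (adjusted p = 0.0538). The analog was itself lower than vehicle in that list (adjusted p = 0.000261, and adjusted p = 0.0968 with an estimated correlation). Summed over the families the level was 29.0 CPM with BRM014, 14.5 with the analog and 33.9 in vehicle, where DMSO 1 h had 21.1.

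Immediate early transcripts were high after BRM014 was removed at 1 h, some of them already before. Fos rose from 3.60 CPM in vehicle to 11.5 at 30 min after washout (1.67 ± 0.16, adjusted p = 1.69e-07) and 12.8 at 1 h (1.83 ± 0.16, adjusted p = 2.07e-08), and Atf3 from 26.4 to 85.7 and 81.2 (1.70 ± 0.09 and 1.62 ± 0.09; 2 libraries per group). Before washout, at 1 h of BRM014, both were above vehicle (Fos 6.34 CPM, 0.81 ± 0.17, adjusted p = 0.0176; Atf3 37.8 CPM, 0.52 ± 0.09, adjusted p = 0.00261). The analog had raised Fos to 6.45 CPM (0.84 ± 0.17, adjusted p = 0.0414). From BRM014 1 h to 1 h of washout Fos rose by 1.01 ± 0.15 and Atf3 by 1.10 ± 0.09. Of 21 immediate early genes 11 rose and 0 fell at 1 h (11 and 1 adjusted over the list alone; adjusted p = 7.47e-09, and 0.00443 with an estimated correlation). Of 14 endoderm genes 8 rose and 0 fell, led by the basement membrane genes Lamb1 and Col4a2 (both 0.57 ± 0.07; 9 and 0 adjusted over the list alone; adjusted p = 1.58e-10, and 0.00994 with an estimated correlation). Sterol genes were up as well (9 of 18 higher, 0 lower; 11 and 0 adjusted over the list alone; Insig1 0.59 ± 0.06; adjusted p = 2.26e-10, and 0.000426 with an estimated correlation). So were p53 targets (4 of 18 higher, 0 lower; 7 and 0 adjusted over the list alone; adjusted p = 0.000663, and 0.00893 with an estimated correlation). Chac1 fell from 17.4 to 5.86 CPM (-1.56 ± 0.15, adjusted p = 1.12e-07). No vehicle-treated cells were washed, and the washed cells were collected 30 min or 1 h later than DMSO 1 h and BRM014 1 h. Time, a continued response to BRM014 and the medium change therefore cannot be set apart from removal of the compound. After 3 h of BRM014 without washout Atf3 and sterol genes were also higher and Chac1 lower.

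Against vehicle 671 genes were called 30 min after that washout and 1014 at 1 h, and against BRM014 at 1 h 738 and 498. The 9 genes that BRM014 raised over the analog at 1 h went from a median of 0.47 ± 0.06 over vehicle to 0.24 ± 0.02 and 0.20 ± 0.01 at 30 min and 1 h after washout, and the 11 it lowered from -0.41 ± 0.05 to -0.15 ± 0.02 and 0.03 ± 0.02 (SD between libraries). The genes were chosen with the BRM014 libraries that give the starting medians, so part of the move toward 0 follows from the choice. Only 5 of the 9 and 6 of the 11 were called against vehicle. Arc, for example, stood at 50.3 CPM with BRM014, 50.2 in vehicle and 72.8 with the analog. Genes called against vehicle instead had medians of 0.27 and -0.36 at 30 min and 0.41 and -0.42 at 1 h, which turns the last direction. At 30 min the count against vehicle was 199 and 163 without DMSO 1 h replicate 1 or 2 and 1080 and 166 without washout 30 min replicate 1 or 2. Against BRM014 it was 187 without BRM014 1 h replicate 2 and 1336 and 162 without washout 30 min replicate 1 or 2. At 1 h it was 405, 351 and 345 against vehicle without DMSO 1 h replicate 1, DMSO 1 h replicate 2 or washout 1 h replicate 2. Against BRM014 it was 299, 255 and 229 without BRM014 1 h replicate 1, BRM014 1 h replicate 2 or washout 1 h replicate 2.

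By 6 h of washout after 24 h of BRM014, most of the lowered genes had moved back toward vehicle and some past it. Cells of the 6 h and 24 h washouts were collected later than DMSO 24 h, which was not washed. Time and the medium change therefore cannot be set apart from removal of the compound. Trh went from 11.3 to 317 CPM (4.81 ± 0.10 against BRM014 24 h), above the 199 of vehicle. Kdr, the VEGF receptor of early mesoderm, rose from 2.38 ± 0.4 CPM in vehicle to 40.5 ± 2.42 (4.08 ± 0.22, adjusted p = 1.26e-13), and the primitive streak gene T by 2.49 ± 0.33. Dusp6 and Dusp4, feedback phosphatases of ERK, rose by 1.35 ± 0.06 and 1.56 ± 0.09, with 10 of 12 in the FGF/ERK list higher and 1 lower, the same adjusted over the list alone (adjusted p = 0.00121, and adjusted p = 0.184 with an estimated correlation). Chac1 fell from 24.8 to 3.39 CPM (-2.85 ± 0.16), and of 14 stress response genes 10 fell and 3 rose, the same adjusted over the list alone (adjusted p = 0.000281, and 0.0151 with an estimated correlation). That list was also lower than with BRM014 24 h (median -0.56; adjusted p = 0.0152, and adjusted p = 0.0708 with an estimated correlation). Against DMSO 1 h it was not called (median -0.16, adjusted p = 0.0878). The p53 targets rose from BRM014 24 h (14 of 18 higher, 3 lower, the same adjusted over the list alone; median 0.65; adjusted p = 0.000106, and 0.00647 with an estimated correlation). The test called 4983 genes against vehicle, 2605 higher and 2378 lower, and 6090 against BRM014 24 h.

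Zscan4c, a marker of the 2-cell-like state, rose from 4.49 ± 0.722 CPM in vehicle to 16.2 ± 2.3 at 6 h and 33.9 ± 1.59 at 24 h after washout (2.91 ± 0.16 at 24 h, adjusted p = 2.71e-13). All 11 measured members of that list rose at both times, the same adjusted over the list alone, with medians of 1.84 (adjusted p = 8.58e-06, and adjusted p = 0.0521 with an estimated correlation) and 2.86 (adjusted p = 4.26e-16, and 0.000849 with an estimated correlation). These genes are near-identical copies, and summed over 26 genes of the families the level was 33.9 ± 1.26 CPM in vehicle, 117 ± 7 at 6 h and 235 ± 3.97 at 24 h. Krt7 and Krt18, keratins of trophectoderm and simple epithelium, rose at 24 h (1.84 ± 0.18 and 1.06 ± 0.07), with 4 of 10 trophectoderm genes higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.000671, and adjusted p = 0.0838 with an estimated correlation). Ano3, a membrane scramblase gene, fell (-2.03 ± 0.16, adjusted p = 2.11e-10). Of 18 p53 targets 16 were lower (17 adjusted over the list alone; adjusted p = 2.09e-16, and 1.06e-05 with an estimated correlation) than DMSO 24 h, with medians of -0.19 and -0.15 over DMSO 1 h, after 0.43 and 0.40 at 6 h of washout.

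**Figure D3:**
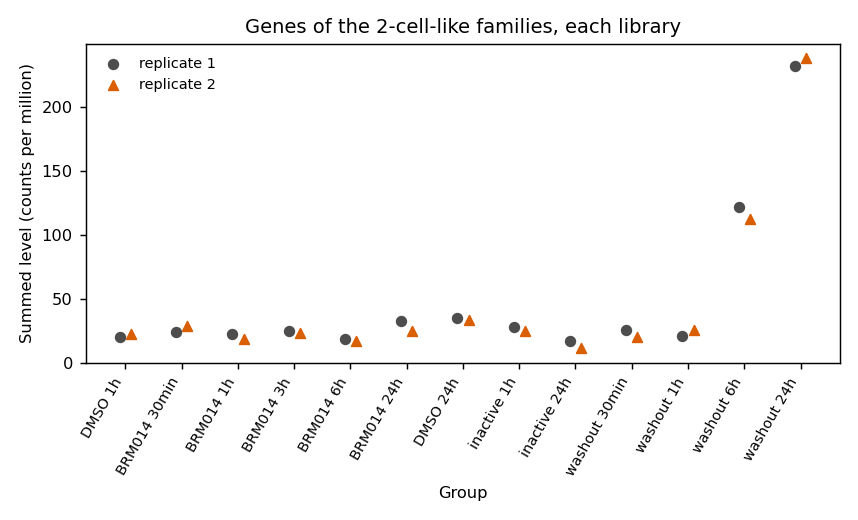
Summed CPM of 26 genes of the 2-cell-like families in each of the 26 libraries of the first batch, 1 point per library. The libraries collected 24 h after washout stand at 232 and 238 and those at 6 h at 122 and 112, against 33.0 and 34.8 in DMSO 24 h.

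By 24 h after washout most genes of the 24 h response were near vehicle, which was collected earlier and not washed. The 601 genes raised at least 2-fold in the second batch went from a median of 1.24 ± 0.01 with BRM014 to 0.58 ± 0.02 at 6 h and 0.12 ± 0.02 at 24 h (SD between libraries). The 950 lowered genes went from -1.54 to -0.21 ± 0.03 and -0.11 ± 0.04, and at 6 h 171 of these were called above vehicle. Inhbb rose by 4.29 ± 0.09 and Fgfbp1 fell by 3.30 ± 0.10 from BRM014 24 h to 24 h after washout. Against vehicle 2181 genes were called, 1115 higher and 1066 lower, and 6305 against BRM014 24 h. The count against vehicle was 1132 without DMSO 24 h replicate 2 and 1405 and 1420 without washout 24 h replicate 1 or 2. Over all called genes whatever their fold the medians were 0.14 and -0.11 at 6 h and 0.02 and -0.05 at 24 h. Without washout 24 h replicate 2 the median of the lowered genes at 24 h was -0.06.

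In the Ino80ko libraries Ino80 was lower but present, at 122 ± 3.81 CPM against 170 ± 0.184 in wild type (-0.48 ± 0.07, adjusted p = 1.44e-05, 2 libraries per group); the counts were 4892 and 4995 with DMSO and 5049 and 5557 with BRM014. It was lower by as much in Snf2hko (123 ± 3.66 CPM, -0.46 ± 0.07, adjusted p = 1.27e-05), so its RNA level does not settle the Ino80ko genotype. Smarca5, the gene that Snf2hko is named for, was listed at 0 counts in each of the 38 libraries, wild type included, so that genotype could not be checked at its gene. Smarca2, the BRM ATPase, fell in Ino80ko (4.25 against 10.6 CPM, -1.32 ± 0.12, adjusted p = 4.08e-08) and rose in Snf2hko (44.6 ± 1.18, 2.07 ± 0.10, adjusted p = 4.05e-12).

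Ino80ko cells lost the stem cell transcript Lncenc1 (15.6 against 205 CPM, -3.72 ± 0.09, adjusted p = 2.54e-15) and the autotaxin gene Enpp2 (0.322 against 13.3, -5.36 ± 0.23, adjusted p = 1.56e-12). The imprinted gene Nnat had 0 counts against 10.3 CPM in wild type, at least 279-fold lower. Irak3, a brake on interleukin receptor signalling, rose from 11.9 ± 0.676 to 85.0 ± 1.71 CPM (2.83 ± 0.08, adjusted p = 2.74e-14), and Bmp4 from 75 to 241 (1.68 ± 0.07). Grin2a, Synpo2l, Lims2, Wnt6, Cntfr, Kbtbd11 and Rapgef3 rose by 2.39 to 3.42, and Vrtn, Fmr1nb, Ccno, Dppa3 and Ankrd1 fell by 3.25 to 4.11. Of 15 endoderm genes 11 fell and 0 rose, the same adjusted over the list alone (Gata4 -1.46 ± 0.10, Foxa2 -1.61 ± 0.14; adjusted p = 0.000147, and adjusted p = 0.418 with an estimated correlation). Lefty1 fell by 1.39 ± 0.10, with 9 of 13 Nodal and BMP targets lower and 2 higher (10 and 2 adjusted over the list alone; adjusted p = 0.0406, and adjusted p = 0.474 with an estimated correlation). That call was lost without DMSO 24 h Ino80ko replicate 1 (adjusted p = 0.0562). The test called 5905 of 13130 genes, 2900 higher and 3005 lower.

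Snf2hko cells gained endoderm transcripts, and genes of the fibroblast and feeder list with them. Cubn, the endocytic receptor of visceral endoderm, rose from 65.4 ± 2.36 to 702 ± 15.2 CPM (3.42 ± 0.11, adjusted p = 2.61e-13), its partner Amn from 4.17 to 58.7 (3.81 ± 0.13) and the endoderm factor Gata6 from 19.0 to 97.3 (2.36 ± 0.08). Of 15 genes 13 rose and 0 fell, the same adjusted over the list alone (adjusted p = 2.04e-07, and adjusted p = 0.157 with an estimated correlation). Dkk1, a secreted Wnt inhibitor, rose from 1.82 to 35.4 CPM (4.27 ± 0.12, adjusted p = 1.33e-15), and the matrix gene Tnc from 0.215 to 15.7 (6.16 ± 0.26). Sohlh2, a germ cell regulator, fell from 27.8 to 0.810 CPM (-5.09 ± 0.16), and the protease gene Prss41 had 3 counts against 702 (253-fold lower, 95% counting interval 86 to 1230). Core pluripotency genes were lower in 12 of 17 and higher in 0 (13 and 0 adjusted over the list alone; Dppa2 -0.60, Tdgf1 -0.48; adjusted p = 0.00205, and adjusted p = 0.157 with an estimated correlation). Sterol genes were higher in 15 of 18 and lower in 2 (16 and 2 adjusted over the list alone; Msmo1 1.09; adjusted p = 0.000172, and adjusted p = 0.17 with an estimated correlation). Fibroblast and feeder markers were higher in 7 of 10 and lower in 0, the same adjusted over the list alone (median 0.76; adjusted p = 0.0177, and adjusted p = 0.157 with an estimated correlation), and p53 targets in 11 of 18 and 3 (12 and 3 adjusted over the list alone; adjusted p = 0.0202, and adjusted p = 0.341 with an estimated correlation). The Y-linked genes Uty and Eif2s3y were also among the largest falls (-6.75 ± 0.16 and -4.85 ± 0.11). The lines thus differ in more than the labelled gene, which could not be checked. Differences between them, in level or in response to BRM014, cannot be assigned to loss of Snf2h. The test called 7425 genes, 3793 higher and 3632 lower.

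BRM014 acted in the same direction on most called genes in all 3 genotypes. Across 13130 genes its effect in Ino80ko correlated with that in wild type of the same batch at 0.65, and in Snf2hko at 0.56. Of genes called in both, 97.6% and 86.9% moved the same way, and against the wild type of the first batch 94.5% and 91.7% did. It called 5847 genes in Ino80ko, where Themis, a regulator of T cell receptor signalling, rose (3.12 ± 0.14) and Igsf21 fell from 47.9 to 1.34 (-5.16 ± 0.13, adjusted p = 7.69e-16). In Snf2hko it called 7470, where the protease gene Ctsc rose from 38.5 to 457 CPM (3.57 ± 0.08, adjusted p = 7.94e-17) and Tgm1 fell from 208 to 6.6 (-4.98 ± 0.09, adjusted p = 6.1e-18). Hox genes, repressed by Polycomb in stem cells, were called higher in 12 of 13 and lower in 0 in Snf2hko, the same adjusted over the list alone (median 2.70; adjusted p = 0.000211, and adjusted p = 0.0845 with an estimated correlation).

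Tests of the difference between genotypes called 1186 of 13130 genes for Ino80ko and 4281 for Snf2hko. In Ino80ko Pim2, a survival kinase gene, responded more positively than in wild type (1.86 ± 0.17, adjusted p = 1.4e-06), and Fgfr3, an FGF receptor, responded more negatively (-2.76 ± 0.14, adjusted p = 6.66e-10). In Snf2hko Sema6a, an axon guidance gene, responded more positively (3.10 ± 0.25, adjusted p = 3.73e-08) and Tcf23, a bHLH factor, more negatively (-4.30 ± 0.46, adjusted p = 1.04e-06). The Ino80ko count was 678 and 739 without DMSO 24 h Ino80ko replicate 1 or 2, 706 without BRM014 24 h wild-type replicate 3, and 753 and 775 without BRM014 24 h Ino80ko replicate 1 or 2.

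The other remodeller lines showed little relation to BRM014 across genes. The fold change of Ino80ko over wild type correlated with that of BRM014 at 24 h in the first batch, which shares no library, at 0.04 over 12368 genes, and that of Snf2hko at -0.08. Of 3096 and 3695 genes called in both, 55.3% and 47.7% moved the same way. Over 8570 genes with a drug effect from the same vehicle libraries the correlations were -0.04 and 0.05 (covariances -0.012 and 0.023). In simulated noise without real changes the shared libraries alone gave a correlation of 0.49 but a covariance of 0.007. Real changes add to the variance, so 0.49 is not the shift that sharing gives in the real data. For Snf2hko the sign turned between choices, from -0.104 in well-expressed genes to 0.084 with drug libraries of the second batch, which share vehicle. The same choices gave 0.02 and 0.109 for Ino80ko.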

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

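The tests of chance splits were set before their results were seen, while those weighing the p53 targets and the inactive analog were chosen after.

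Responses to BRM014 differed by a direct test of the difference in 4 comparisons. For Ino80ko against wild type, the response to BRM014 differed in 1186 genes, with Fam167a (2.28), Vrtn (1.93), Enpp2 (1.86) and Pim2 (1.86) responding more positively and Fgfr3 (-2.76), Krt19 (-2.54), Prrx2 (-2.38), Nkx6-2 (-2.35) and Sorcs2 (-2.30) more negatively. The count was 678 without DMSO 24 h Ino80ko replicate 1, 739 without its replicate 2, 706 without BRM014 24 h wild-type replicate 3, and 753 and 775 without BRM014 24 h Ino80ko replicate 1 or 2. As lists, endoderm (median -0.87), Nodal and BMP (-0.38) and p53 targets (-0.25) responded more negatively and stress response (0.30), sterol (0.27) and xenobiotic genes (0.48) more positively (adjusted p = 1.32e-06, 0.0303, 0.00581, 0.00239, 0.00123 and 0.0339), but each had an adjusted p = 0.305 with an estimated correlation. The xenobiotic call was also lost with a replicate block (adjusted p = 0.0664) and without any of 4 of the 8 libraries (up to 0.141), the Nodal and BMP call without DMSO 24 h wild-type replicate 4 or BRM014 24 h wild-type replicate 3 (up to 0.0638), and the p53 call without the latter (0.0638).

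For Snf2hko the response differed in 4281 genes, with Sema6a (3.10), Trpa1 (2.92), Mmp25 (2.64) and Sema3c (2.60) more positive and Tcf23 (-4.30), Calca (-3.55), Nkx6-2 (-3.45) and Sirpa (-3.05) more negative. Sterol genes (0.36) and Hox genes (1.20) responded more positively and ribosomal protein genes (-0.39) more negatively as lists (adjusted p = 0.000593, 0.000593 and 0.00346; adjusted p = 0.383, 0.123 and 0.617 with an estimated correlation).

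Between 1 h and 24 h the response differed in 3952 genes, with Pm20d2 (3.22), Coch (3.19), Fgfbp1 (2.89), Kitl (2.87) and Meis2 (2.76) more positive at 24 h and Inhbb (-4.57), Aqp8 (-4.51), Igsf21 (-4.26), Krt17 (-4.04) and Trh (-4.01) more negative. Germline genes (0.55) were more positive (adjusted p = 0.000353, and adjusted p = 0.293 with an estimated correlation), and p53 targets (-0.91) and sterol genes (-0.49) more negative (adjusted p = 1.3e-06 and 3.59e-06, and 0.00136 and 0.00282 with an estimated correlation).

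Between batches the 24 h response of wild type differed in 408 genes, with Mmrn2 (1.67), Ano3 (1.65), Plk2 (1.56), Ak1 (1.45) and Btg2 (1.43) more positive in the second and Thbs2 (-2.49), Trim43b (-1.90), Slc5a5 (-1.51), Cthrc1 (-1.47) and Vrtn (-1.46) more negative. The count was 182 and 118 without BRM014 24 h replicate 1 or 2, 181 and 207 without its replicate 3 or 4, 678, 722, 260 and 199 without DMSO 24 h replicate 1, 2, 3 or 4. As lists, p53 targets (0.70) and endoderm genes (0.49) were more positive and 3 neural genes (-0.68) more negative (adjusted p = 7.64e-12, 0.00106 and 0.0101; adjusted p = 0.18, 0.541 and 0.396 with an estimated correlation). Among 46 tests for a sample far from the others of its group, which chance passes about 1 in 20 times, 2 were met: the total of BRM014 24 h replicate 3 (40.8 M counts, others of its group over both batches 20 to 21.9) and Skor1 in DMSO 24 h replicate 1 (8.91 CPM, others 11.1 to 11.3). The first reflects the depth of the batches: 40.8 M lies near the median of the second batch, 41.3, in which BRM014 24 h replicate 4 stands apart with 21.9 M (the other 11 libraries have 37 to 44.5).

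The p53 targets had a median of -0.91 against DMSO 24 h in the first batch and -0.03 in the second, a difference called between batches with the preset correlation (adjusted p = 7.64e-12) but not with an estimated one (adjusted p = 0.18). A single vehicle library out of place is argued against, as both DMSO 24 h libraries of the first batch stood above DMSO 1 h, by 0.43 and 0.54. High vehicle libraries as the whole cause cannot be told apart from a fall with BRM014: the BRM014 24 h libraries lay below DMSO 1 h, at -0.44 and -0.41, and the small difference from the analog at 24 h, -0.17, decides nothing because the analog is not shown to be inert and was itself low (-0.70 against DMSO 24 h). DMSO 1 h is no matched reference either, being another time. Inhibition by BRM014 cannot be told apart from other sources. The targets rose by 0.65 from BRM014 24 h to 6 h after washout, where they stood as high as DMSO 24 h (0.43 and 0.40 over DMSO 1 h), but 24 h after washout they were low again (-0.19 and -0.15, and -0.68 against DMSO 24 h). At 6 h of BRM014 the list was called lower against the mean of vehicles (adjusted p = 0.00183) but not against DMSO 1 h alone (-0.10 and -0.12 per library, adjusted p = 0.242). At 1 h after the short washout it was called higher than vehicle (adjusted p = 0.000663; 0.12 and 0.20 per library), although 1 h of BRM014 had not lowered it (0.02 and 0 per library). With no washed vehicle, both stay open.

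The inactive analog changed 2306 genes at 24 h, in part those that BRM014 changed. A low or high vehicle as the source of this overlap is argued against by the slope of the vehicle's own change on the BRM014 effect of the other batch. It was 0.032, against 0.214 and 0.218 for the analog libraries. For calls outside the overlap the slope decides nothing. The p53, 2-cell-like and germline lists had medians of -0.70, -1.24 and 0.30 with the analog against DMSO 24 h. From DMSO 1 h to DMSO 24 h they had moved the opposite way (0.46, 0.59 and -0.30), though stress response genes rose in both (0.17 and 0.45). A high or low vehicle stays open for those 3 lists. RNA of BRM014-treated cells mixed into the analog libraries is argued against by the share of the BRM014 change reached, 46.2% for 678 lowered and 12.2% for 371 raised genes, a ratio of 3.79 where mixing gives 1. The correlation of 0.42 with the BRM014 effect in libraries that share none is consistent with the analog, or active compound within it, acting weakly on the same genes. The overlap is partial. The p53 and sterol lists were lower with both compounds in the first batch. With the analog stress response genes were higher (camera adjusted p = 0.00431, and 0.0371 with an estimated correlation). Endoderm genes were lower (adjusted p = 4.8e-05, and adjusted p = 0.0975 with an estimated correlation). With BRM014 neither of these 2 lists was called (adjusted p = 0.845 and 0.693). Purity and residual activity of the analog were not measured here and stay open.

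Of 34 splits of the 8 libraries, the real one included, 1 gave as many as the real 5842 genes, and the highest of the others gave 0. The other splits mix drug and vehicle libraries within a group, where the drug effect adds to the spread. Few calls follow from that, so the splits cannot exclude chance as the source of the 24 h calls. Agreement between the batches, which share no library, argues against chance: of 3836 genes called in both, 3780 moved the same way. For the gene lists chance cannot be excluded, since 12 of the 34 splits gave as many as the 3 called, the highest of the others gave 5, and the split by batch gave 6 without a batch term. The germline, Wnt and sterol calls at 24 h rest on the preset correlation.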

How the results depend on the processing

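The lists with single libraries left out, and those at 3 h, 6 h and 6 h of washout against a single vehicle, were the only alternatives chosen after the data were examined. No count of called genes changed by more than 1.5-fold under RLE factors (28 comparisons), library totals (6), no batch term (1; 5056 genes for the 24 h effect), or either vehicle alone (2 each). DESeq2 kept 27 of 28, the exception being inactive 1 h (44). Without a filter on low counts 22 of 28 were kept, the others being BRM014 30 min 2, BRM014 1 h 154, inactive 1 h 80, BRM014 against inactive 1 h 52, washout 30 min against BRM014 1110 and the batch difference 632; the cause was not tested. With only the compared libraries fitted 3 of 5 were kept, the others being BRM014 1 h 49 and inactive 24 h 996, where fewer libraries estimate the spread.

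Replicate numbers are not shown to pair libraries: between groups that share numbers the correlation of replicate differences had a median of -0.007 in the first batch and 0.014 in the second. Values ran from -0.446 to 0.561 in the first, with 23 of 78 group pairs above 0.1 and 28 below -0.1, and from -0.157 to 0.427 in the second. Replicate differences were thus often related between groups, but in either direction. With a replicate block 25 of 26 counts were kept (5528 genes for the 24 h effect), the exception being the batch difference, 810, and 95 gene list calls were made against 96 without it; stress response in BRM014-treated Ino80ko (adjusted p = 0.0693) and xenobiotic response in the Ino80ko interaction (0.0664) were lost. No paired analysis was possible for the genotype comparisons because the lines share no culture in the labels.

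Leaving out single libraries, the lone library being assumed to vary like the other groups, gave 17 to 45 genes for BRM014 1 h, 2 to 26 for BRM014 against inactive 1 h, 2 to 62 for inactive 1 h, 1296 to 2411 for inactive 24 h, 2513 to 3923 for BRM014 3 h, 1147 to 2736 for DMSO 24 h against 1 h, 118 to 722 for the batch difference and 678 to 1150 for the Ino80ko interaction. Washouts gave 163 to 1080 (30 min) and 345 to 899 (1 h) against DMSO, 162 to 1336 and 229 to 403 against BRM014, and 1132 to 2611 at 24 h against DMSO. For the 24 h effect the range was 5163 to 5746 and for the Snf2hko interaction 3180 to 4502. Recovery medians ran from 0.55 to 0.58 and -0.2 to -0.16 (6 h), 0.13 to 0.15 and -0.12 to -0.06 (24 h), -0.19 to -0.16 (30 min, lower genes) and stayed at 0.17 (1 h, higher genes).

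Over all called genes recovery medians were 0.14 and -0.11 at 6 h and 0.02 and -0.05 at 24 h, since smaller changes were taken in. For genes called against DMSO 1 h they were 0.27 and -0.36 at 30 min and 0.41 and, reversed, -0.42 at 1 h; the cause was not tested. The genotype correlations were 0.02 and -0.104 in well-expressed genes and 0.109 and, reversed, 0.084 with drug libraries of the second batch, which share vehicle. Of 107 gene list calls 35 held with an estimated correlation. Of 10764 named-gene values with single libraries left out 9773 stayed called, 991 did not and 0 reversed. Under the other alternatives 1 reversed, Smc1b at 3 h against DMSO 1 h alone (-0.32), a gene that fell by 1.15 ± 0.10 between the 1 h and 24 h vehicle. Without the filter on low counts 2129 of 2161 named values stayed called. Against a single vehicle the lists called at 3 h and 6 h kept their calls except p53 targets at 6 h against DMSO 1 h (adjusted p = 0.242), and at 6 h of washout against DMSO 1 h germline (0.164) and stress response (0.0878) were lost. Effects of depth were not tested by thinning; at this depth 0 counts leave Nnat a bound only, and 3 counts give Prss41 a counting interval of 86 to 1230-fold.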

Other observations

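The tests of the 2-cell-like genes were chosen after the result was seen, and the Y-linked values carry no test.

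The 2-cell-like genes were higher 6 h and 24 h after washout from 24 h of BRM014, and not during 24 h of BRM014 (summed level 29.0 ± 5.51 CPM, vehicle 33.9 ± 1.26, analog 14.5 ± 3.92). Reads shared between near-identical copies are argued against, as the sum over the 26 genes of the families was, 24 h after washout, 6.93 times that of vehicle. Single-copy genes moved alike: Tmem92 stood at 3.46 and 3.82 CPM 24 h after washout against 0.275 and 0.524 in DMSO 24 h, and Sp110 at 2.90 and 2.69 against 0.321 and 0.210. Low vehicle libraries are argued against for the rise at 24 h after washout, where the lowest library was 6.67 times the highest of the first batch outside the washouts. Because 0 vehicle-treated libraries were washed, a rise through removal of BRM014 cannot be told apart from time in culture or the medium change. Unwashed vehicle itself rose in these genes, from a summed level of 21.1 CPM in DMSO 1 h to 33.9 in DMSO 24 h. There 3 of 11 in the list were higher and 0 lower (camera adjusted p = 0.0403, and adjusted p = 0.344 with an estimated correlation).

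In the 4 Snf2hko libraries Uty stood at 0.457 to 0.770 CPM and Eif2s3y at 3.05 to 6.45, against 47.6 to 62.2 and 82.9 to 115 in the 8 other libraries of the second batch.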
